A study of Homo sapiens with 33 samples.

How the data were processed

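The samples were 33 preparations of total RNA from MCF-7, an established line of human breast cancer cells. Per the labels, cells were kept for 48 h in medium with serum stripped of steroids by charcoal and then exposed to 1 of 7 ligands of nuclear receptors for 24 h. Control cells were collected at 0 h, before treatment, so that ligand and 24 h of further culture go together in every comparison against controls. The labels give 3 biological replicates per group. Each preparation was labelled with Cy3 and hybridised to 1 Agilent whole-genome oligonucleotide array of 1 colour. It held 43376 probe spots and, besides these, 1639 control spots. Each treated group was set against the control group that its label names, and the 3 retinoids shared 1 control group, as did R5020 and dexamethasone (DEX).

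Per the file headers, each deposited scanner file holds spot signals as an intensity in arbitrary units, with local background subtracted and spatial trends removed within the array by Agilent Feature Extraction, and with no normalization between arrays. The headers name version 9.5.3.1 and a GenePix 4000B scanner for 24 arrays, and version 10.5.1.1 and an Agilent G2505C scanner for the 9 arrays of R5020, DEX and their control, whereas the submitters' processing notes name version 9.1. On 29 arrays the software had replaced signals at background by surrogate values. A value table deposited by the authors holds log2 signals whose steps after the scanner are not stated. Its column medians lay between 7.14 and 7.19, and each column followed that array's scanner signal with a Spearman correlation across probes of 0.955 to 0.985. It served as an alternative only.

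The processed signal of each spot was divided by the array's 75th percentile of that signal, a floor of 0.015 of that percentile was set, and log2 was taken, so that a level of 0 is the 75th percentile of its array. Spots marked as nonuniform or as outliers were left out, and spots of 1 probe were averaged. The 41000 probes were named through the accession in the annotation of the later design version in the files (23958 probes), through a current symbol (2755) or through an older symbol (1032), and the other 13255 kept the name in the files. This gave 30482 genes, 17843 of them with a symbol of the RefSeq table. For the 7771 genes with several probes, the probe with the highest mean level over the 33 arrays stood for its gene. For the largest rises and falls of each comparison named below, every other tested probe of the gene moved in the same direction, though by much less in CDSN with GW0742 (0.45 against 2.93 on the log2 scale) and MUC5AC with DEX (−1.08 against −2.93). Another probe moved the other way for ASNS with ATRA and between ATRA and each other retinoid, for RARA with all 3 retinoids and for RARG with CD437. Probe coordinates are those of the files, in build hg18. No genome sequence was used.

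A gene was tested where its probe was well above background, by the scanner software's own mark, on each array of at least 1 group of the fit. Tests used lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a call at an adjusted p under 0.05. There were 4 fits, for E2 (6 arrays), the retinoids (12 arrays), R5020 and DEX (9 arrays) and GW0742 (6 arrays). They gave 7 comparisons against controls and 4 direct comparisons of ligands. Intervals are 95% intervals from limma's moderated standard error. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. A signal near background has no measured level. Where no array of 1 group was well above background for a gene, the change is given as at least N-fold, with that group's values raised to the lowest level that was well above background on the same array. The same was done for the dim arrays of a group with 1 or 2 arrays well above background, whose number the text then gives.

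Before the data were examined, 23 gene lists were written from textbook knowledge: genes induced by estrogen, by retinoids, by glucocorticoids or by progestins, genes repressed by estrogen, targets of PPAR and of p53, genes of mitosis, DNA replication, cholesterol synthesis, ribosome biogenesis, the interferon, amino acid, endoplasmic reticulum stress, heat shock and hypoxia responses, immediate early genes, metallothionein genes, nuclear receptor genes, and markers of luminal epithelium, basal epithelium, fibroblasts and leukocytes. Of the 19 progestin-induced genes, 10 also stood in another list, as did 7 of the 25 glucocorticoid-induced genes. Each list with at least 5 tested members was tested against all other genes with camera (limma) at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were alternatives. Fry asks only whether a list's genes move 1 way on balance. The named genes were also chosen by a rule fixed before the data were examined: per ligand the 8 largest rises and the 8 largest falls among genes called and without overlap between the 3 treated and the 3 control values, per direct comparison the 3 largest each way, up to 4 members of each list with the largest change, and the genes of the receptors addressed. Names that are only accessions, clones or reading frame numbers were left out. Exceptions, chosen after their values were seen, were CCDC74B, PLAU, ST8SIA4 and, in a figure, GREB1, and the retinoid-induced genes carried from 1 retinoid comparison into another.

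Per the file headers, the E2 and E2 control arrays shared 3 slides scanned on 3 days, and the ATRA and retinoid control arrays shared 3 slides scanned on 1 day. On these slides arrays with the same replicate number deviated from their group means together, with correlations across genes of 0.517, 0.483 and 0.358 for E2 and of 0.408, 0.711 and 0.309 for ATRA. The numbers were therefore taken to mark pairs in these 2 comparisons, through the shared slides, and in no other. AM580, CD437, R5020, DEX, GW0742, the R5020 and DEX control and the GW0742 control each lay on 1 slide of their own, so for them slide and group cannot be told apart.

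The 75th percentile of the signal ran from 91.1 to 960 between arrays, and 51.1% to 66.1% of spots were well above background. The number of arrays, 3 per group, limits the precision of every value. On simulated data with 200 changed genes, a 2-fold change was recovered for 14.9% of genes in a fit like that of E2, 83.6% for ATRA, 83.6% for AM580, 73.1% for CD437, 86.6% for R5020, 80.6% for DEX and 95.5% for GW0742. A 4-fold change was recovered for 97.0% in the E2 fit. In each simulated comparison 5 to 15 unchanged genes were called, and none of 20 unchanged lists was. The alternatives, planned before the data were examined unless the text says otherwise, were normexp background correction of the mean and background signals (offset 50), scaling on the median, quantile normalization, the authors' value table, no filter on dim probes, a filter on every array, every probe in place of 1 per gene, all 33 arrays in 1 fit, only the 6 arrays of a comparison, a block for replicate number or slide, a 2-fold threshold, and each array left out in turn. Another 100 simulated draws of unchanged groups gave the overlap that a shared control produces with no effect.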

Results

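Expression of 30482 genes was measured in MCF-7 breast cancer cells on 33 arrays, in 7 groups of 3 treated cultures and 4 groups of 3 control cultures. Estradiol (E2) and the progestin R5020 were given at 10 nM, and all-trans retinoic acid (ATRA), AM580, CD437 and dexamethasone (DEX) at 100 nM. For GW0742 the sample labels give 10 nM and the description of the design gives 100 nM. Per the series title, E2 addresses estrogen receptor alpha, ATRA the retinoic acid receptors RARA and RARG, AM580 RARA, CD437 RARG, R5020 the progesterone receptor, DEX the glucocorticoid receptor and GW0742 the receptor PPARD. Levels are log2 signals relative to the 75th percentile of the array, given as mean ± SD of 3 arrays, and changes are log2 fold changes ± SE, with adjusted p-values from limma. Beside an at-least fold, a number such as 1 of 3 counts the arrays of the lower group well above background. Each comparison asked which genes change when 1 receptor is addressed, and direct ones where ligands of the same or a related receptor differ.

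**Figure D1:**
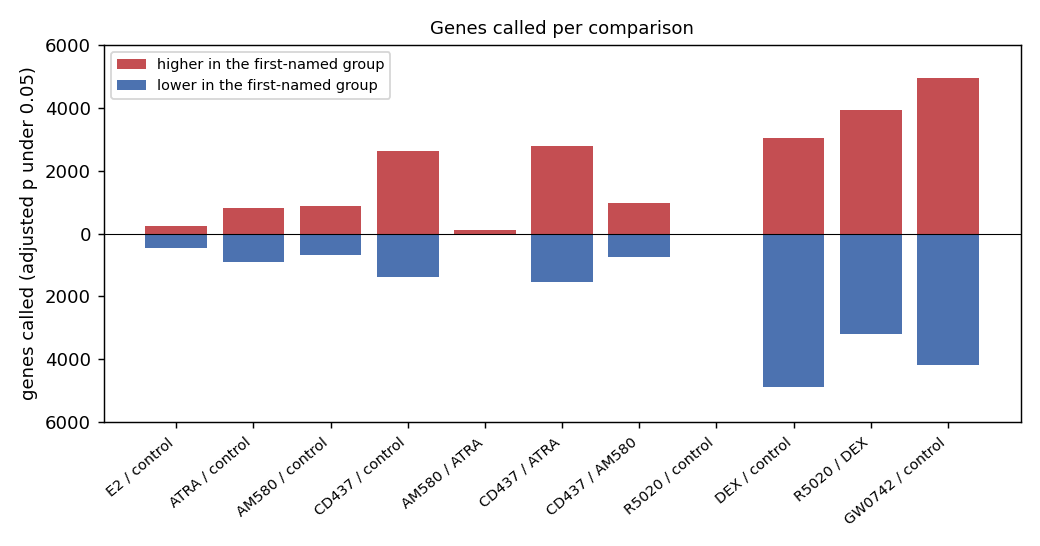
Bars give the number of genes called higher and lower (adjusted p under 0.05) in each of the 11 comparisons. The numbers run from 0 genes for R5020 to 9106 for GW0742.

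With E2, 26 of 39 genes known to be induced by estrogen rose and 10 of 14 known to be repressed by it fell. UGT2B15, an enzyme that joins steroids to glucuronic acid, was at least 11.7-fold higher, at −1.50 ± 0.21 (n = 3; adjusted p = 0.000929), with 1 of 3 control arrays well above background. PGR, the gene of the progesterone receptor, was at least 9.49-fold higher, at −1.30 ± 0.44 (adjusted p = 0.00807), with 2 of 3. BMF, which promotes cell death as a partner of BCL2 proteins, fell from 0.58 ± 0.30 to −2.34 ± 0.26 (change −2.92 ± 0.23, adjusted p = 0.00288). The probes of these genes lie on chromosome 4 at 69195353 to 69195412, chromosome 11 at 100417919 to 100417978 and chromosome 15 at 38167742 to 38167801 (hg18). Among the largest rises were also PDZK1, a scaffold protein (3.78 ± 0.41), the transcription factor EGR3 (3.70 ± 0.54), the metallopeptidase AMZ1 (3.47 ± 0.46), and, with 2 of 3 control arrays well above background, the cadherin CDH26, the peptidoglycan amidase PGLYRP2 and ARHGAP36 (at least 13.95-fold, 9.94-fold and 9.77-fold higher). Among the largest falls were SERHL2 (−2.74 ± 0.35) and the cytochrome P450 CYP2C8 (at least 4.32-fold lower). With 1 of 3 E2 arrays well above background, PCSK2, a protease that matures peptide hormones, was at least 10.1-fold, the sialyltransferase ST6GAL1 at least 7.46-fold, the proton pump subunit ATP6V0A4 at least 6.68-fold, the phospholipase PLCE1 at least 5.57-fold and CLIP4 at least 4.79-fold lower. On the 3 slides that held both groups, the change was −3.14, −3.16 and −2.45 for BMF. The receptor gene ESR1 differed by −0.26 (95% interval −0.69 to 0.16, adjusted p = 0.495). Some calls were lost without 1 array. Without E2 control replicate 3 the adjusted p was 0.0503 for ARHGAP36 with E2, 0.0674 for CDH26 with E2, 0.0702 for EGR3 with E2, 0.0672 for ATP6V0A4 with E2, 0.0792 for PLCE1 with E2 and 0.0502 for SERHL2 with E2. Without E2 replicate 1 it was 0.0525 for CDH26, 0.0635 for EGR3, 0.0631 for ATP6V0A4 and 0.0530 for PLCE1. Without E2 replicate 3 it was 0.0522 for CDH26 and 0.0642 for PLCE1, and without E2 control replicate 1 it was 0.0641 for ATP6V0A4.

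Of 39 tested estrogen-induced genes, 26 rose, none fell and 13 did not pass, with a median change of 1.27. Adjusted over the list alone, 37 rose (camera adjusted p = 1.36e-33, and adjusted p = 0.129 with an estimated correlation). Of 14 estrogen-repressed genes 10 fell and none rose, with a median of −1.76, and adjusted over the list alone 11 fell (camera adjusted p = 1.83e-11, and adjusted p = 0.0439 with an estimated correlation). Besides BMF these included PSCA, a surface antigen (at least 4.74-fold lower, 2 of 3 E2 arrays, adjusted p = 0.0073), and TP53INP1, a gene of the stress response (−1.87 ± 0.23, adjusted p = 0.0085). Of 29 mitosis genes 7 rose and none fell, with a median of 1.09, and adjusted over the list alone all 29 rose (camera adjusted p = 1.29e-20, and adjusted p = 0.187 with an estimated correlation). Of 35 DNA replication genes 6 rose and none fell, with a median of 0.80, and adjusted over the list alone 28 rose (camera adjusted p = 8.45e-16, and adjusted p = 0.187 with an estimated correlation). The kinetochore motor CENPE rose by 1.47 ± 0.21 (adjusted p = 0.013), and ORC1, which marks origins of replication, rose by 1.34 ± 0.23 (adjusted p = 0.023). Without E2 control replicate 1 or 3 the adjusted p of CENPE with E2 was 0.0580 or 0.0540. Without E2 replicate 1 or 3 or control replicate 1 or 3 that of ORC1 with E2 was 0.0969, 0.0835, 0.0760 or 0.0766. Against their mean, E2 control replicates 1, 2 and 3 had medians of −0.417, 0.441 and 0.0116 for mitosis genes. Genes raised by E2 had −0.211, 0.334 and −0.109. On the 3 slides the medians were 1.59, 1.12 and 1.44 for estrogen-induced genes, −1.88, −1.61 and −1.54 for estrogen-repressed genes, 1.46, 0.648 and 1.18 for mitosis genes and 1.08, 0.546 and 0.927 for DNA replication genes. With the slides as a block the adjusted p-values of these lists were 1.27e-25, 6.55e-08, 1.15e-16 and 3.91e-14.

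Limma called 699 of 16989 genes (4.11%), 237 higher and 462 lower with E2, of which 574 changed at least 2-fold. With replicates as blocks, since the slides pair the arrays, 1472 genes were called, 692 of them among the 699. The count was 144 without E2 replicate 1, 262 without E2 replicate 3, 169 without control replicate 1 and 149 without control replicate 3. It was 22 with normexp correction, 139 with no filter on dim probes, 344 in the authors' value table and 4449 with all 33 arrays in 1 fit.

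**Figure D2:**
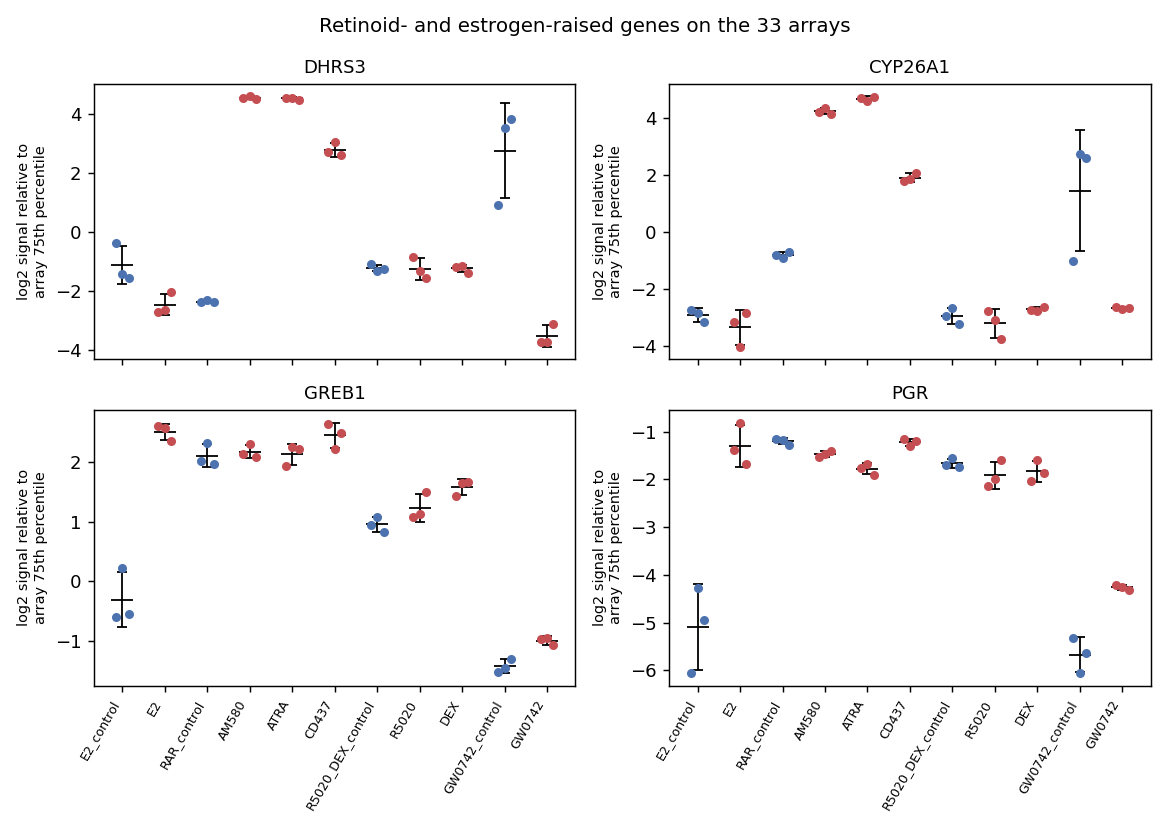
Points give the log2 level, relative to the 75th percentile of the array, of DHRS3, CYP26A1, GREB1 and PGR on each of the 33 arrays, and bars give the mean ± SD of each group (blue for control, red for treated). DHRS3 lies at 4.53 ± 0.04 with ATRA and at −2.36 ± 0.03 in its control, and in the arrays labelled GW0742 control it spreads around 2.76 ± 1.61.

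With ATRA, 2 enzymes of retinoid metabolism were among the 8 largest rises. DHRS3, which reduces retinal to retinol, rose 118-fold, from −2.36 ± 0.03 to 4.53 ± 0.04 (n = 3; change 6.89 ± 0.11, 95% interval 6.64 to 7.13, adjusted p = 3.25e-11). CYP26A1, which breaks down retinoic acid, rose 44.5-fold, from −0.80 ± 0.10 to 4.68 ± 0.08 (change 5.48 ± 0.10, adjusted p = 7.08e-11). Their probes lie on chromosome 1 at 12550697 to 12550756 and on chromosome 10 at 94827003 to 94827062 (hg18). The sphingomyelinase SMPD3 (5.55 ± 0.12) and the ribonuclease ANG (4.84 ± 0.09) rose as well, and RNASE4 was at least 29.2-fold higher (1 of 3 control arrays). The pepsinogen gene PGC was at least 39.98-fold, the copper carrier CP at least 22.0-fold and the homeobox gene HOXB2 at least 17.5-fold higher. BMP5, a signalling ligand, fell (−3.29 ± 0.13). TNFRSF11B, the decoy receptor osteoprotegerin, was at least 13.7-fold (2 of 3 ATRA arrays, adjusted p = 1.54e-07) and the fatty acid receptor CD36 and the collagen COL4A6 at least 9.42-fold and 9.02-fold lower (1 of 3). CLIC3 was at least 11.0-fold, ANXA1 at least 6.13-fold, LRRC4C at least 5.91-fold and the amino acid transporter SLC7A8 at least 5.40-fold lower. On the 3 slides that held both groups, the change was 6.93, 6.86 and 6.86 for DHRS3 and 5.51, 5.48 and 5.44 for CYP26A1. The receptor genes differed by −0.23 for RARA (95% interval −0.52 to 0.06, adjusted p = 0.399, other probe 0.11) and −0.23 for RARG (adjusted p = 0.189), and RARB was not well above background in any of the 12 arrays of this fit.

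Of 25 tested retinoid-induced genes, 15 rose, 1 fell and 9 did not pass, with a median change of 1.11, and adjusted over the list alone 19 rose and 2 fell (camera adjusted p = 8.03e-23, and adjusted p = 0.00179 with an estimated correlation). Besides DHRS3 and CYP26A1, STRA6, the receptor for retinol uptake, was at least 10.1-fold higher (1 of 3 control arrays). Of 24 interferon response genes 14 fell and none rose, with a median of −0.47, and adjusted over the list alone 18 fell (camera adjusted p = 8.28e-14, and adjusted p = 0.0458 with an estimated correlation). Among them were IFI44L (−1.06 ± 0.12) and the antiviral gene IFIT3 (−0.82 ± 0.14). Of 19 amino acid response genes 7 rose and none fell, with a median of 0.38, and adjusted over the list alone 17 rose (camera adjusted p = 1.64e-12, and adjusted p = 0.00984 with an estimated correlation). These included DDIT4 (1.39 ± 0.13), PHGDH, of serine synthesis (1.25 ± 0.12), and the asparagine synthetase ASNS (1.31 ± 0.10), of which another probe was lower (−0.56). Of 16 hypoxia genes 6 rose, and adjusted over the list alone 10 rose, with a median of 0.41 (camera adjusted p = 3.7e-06, and adjusted p = 0.279 with an estimated correlation). Among them were hexokinase HK2 (1.45 ± 0.17) and the angiogenic factor VEGFA (1.03 ± 0.12). Of 9 basal epithelial markers 5 fell, and adjusted over the list alone 6 fell, with a median of −0.54 (camera adjusted p = 5.24e-07, and adjusted p = 0.00984 with an estimated correlation), among them caveolin CAV1 (−2.73 ± 0.08) and keratin KRT17 (−1.75 ± 0.18). Of 12 immediate early genes 4 fell, and adjusted over the list alone 4 fell, with a median of −0.18 (camera adjusted p = 0.000421, and adjusted p = 0.0458 with an estimated correlation), among them EGR1 (−1.53 ± 0.10) and KLF6 (−1.38 ± 0.15). Of 11 estrogen-repressed genes 7 rose and 1 fell, and adjusted over the list alone 8 rose and 1 fell, with a median of 0.51 (camera adjusted p = 4.09e-05, and adjusted p = 0.00984 with an estimated correlation), led by the transcription factor SOX9 (1.63 ± 0.10), while KLF4 fell (−0.80 ± 0.13). In the 3 control cultures shared by the retinoids, genes lowered by E2 lay at a median of −1.55, −1.60 and −1.55 relative to the E2 control, close to the E2-treated cells (−1.49, −1.46 and −1.39).

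Small shifts were seen in 3 further lists. Of 30 mitosis genes none passed, with a median of −0.15 (camera adjusted p = 0.00331, and adjusted p = 0.185 with an estimated correlation). Of 35 DNA replication genes 2 fell, and adjusted over the list alone none did, with a median of −0.12 (camera adjusted p = 0.0125, and adjusted p = 0.324 with an estimated correlation). Of 23 cholesterol synthesis genes 1 fell, also when adjusted over the list alone, with a median of −0.13 (camera adjusted p = 0.0457, and adjusted p = 0.409 with an estimated correlation). For the cholesterol synthesis genes with ATRA the adjusted p was 0.138 without ATRA replicate 2, 0.130 without control replicate 1 and 0.0674 without control replicate 3. On the 3 slides the medians were 1.04, 1.18 and 1.13 for retinoid-induced genes, −0.498, −0.519 and −0.390 for interferon genes, 0.374, 0.426 and 0.445 for amino acid response genes, 0.730, 0.218 and 0.408 for hypoxia genes and −0.517, −0.563 and −0.575 for basal markers. With the slides as a block these lists had adjusted p-values of 1.32e-10, 2.13e-10, 2.23e-09, 8.46e-05 and 9.6e-05. Immediate early genes had medians of −0.138, −0.253 and −0.243 (adjusted p = 0.00328) and estrogen-repressed genes of 0.455, 0.455 and 0.569 (adjusted p = 0.00304). Limma called 1722 of 17832 genes (9.66%), 803 higher and 919 lower, of which 417 changed at least 2-fold. With slides as blocks over the 6 arrays, a fit added after the data were seen, 3298 were called, 1675 of them among the 1722. The count was 1121 without control replicate 3 and 157 with normexp correction.

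With AM580, too, enzymes of retinoid metabolism were among the largest rises. DHRS3 rose 121-fold (change 6.91 ± 0.11, n = 3, adjusted p = 3.12e-11) and CYP26A1 32.8-fold (5.03 ± 0.10, adjusted p = 2.19e-10). SMPD3 (4.79 ± 0.12), ANG (4.14 ± 0.09) and CYP26B1, a second enzyme that breaks down retinoic acid (3.77 ± 0.14), rose too. RNASE4 and the phosphatase PTPRH were at least 17.8-fold and 14.8-fold higher (1 of 3 control arrays), and HOXB2 and HOXB3 at least 17.1-fold and 15.3-fold higher. CAV1, which coats caveolae, fell from 2.0 ± 0.04 to −0.49 ± 0.00 (change −2.49 ± 0.08, adjusted p = 4.8e-09). BMP5 (−2.96 ± 0.13), CD36 (−2.82 ± 0.13), TNFRSF11B (−2.81 ± 0.19), CLIC3 (−2.76 ± 0.16) and COL4A6 (−2.65 ± 0.20) fell, and ANXA1 (1 of 3 AM580 arrays) and SLC7A8 were at least 6.21-fold and 5.36-fold lower. Of 25 retinoid-induced genes 16 rose and 1 fell, and adjusted over the list alone 18 rose and 2 fell, with a median of 1.0 (camera adjusted p = 6.96e-21, and adjusted p = 0.00246 with an estimated correlation). Of 9 basal markers 5 fell, and adjusted over the list alone 6 fell, with a median of −0.75 (camera adjusted p = 3.6e-07, and adjusted p = 0.0134 with an estimated correlation). That median turned to 0.154 with normexp correction. Of 12 immediate early genes 5 fell, among them KLF6 (−1.07 ± 0.15), and adjusted over the list alone 5 fell and 1 rose, with a median of −0.36 (camera adjusted p = 0.00124, and adjusted p = 0.102 with an estimated correlation). Of 30 mitosis genes 2 fell, and adjusted over the list alone 4 fell, with a median of −0.18 (camera adjusted p = 0.000112, and adjusted p = 0.102 with an estimated correlation). Of 8 metallothionein genes, which bind zinc and copper, 3 rose, also when adjusted over the list alone, with MT1E at 0.65 ± 0.12 and a median of 0.34 (camera adjusted p = 0.00493, and adjusted p = 0.594 with an estimated correlation), a median that turned to −0.0799 with normexp correction. Of 11 estrogen-repressed genes 3 rose and 1 fell, and adjusted over the list alone 5 rose and 1 fell, with a median of 0.34 (camera adjusted p = 0.0443, and adjusted p = 0.135 with an estimated correlation). For the estrogen-repressed genes with AM580 the adjusted p was 0.0706 without control replicate 2, 0.0525 without control replicate 3 and 0.117 without AM580 replicate 1. Of 24 interferon genes 2 fell and none rose, with a median of 0.02 (camera adjusted p = 0.759), and of 19 amino acid response genes 3 rose (camera adjusted p = 0.251). The receptor gene RARA differed by −0.47 (95% interval −0.76 to −0.18, adjusted p = 0.0526), and its other probe by 0.20. For RARA with AM580 the adjusted p was 0.0387 without control replicate 2 and 0.0270 without AM580 replicate 2. Limma called 1541 genes (8.64%), 872 higher and 669 lower, of which 400 changed at least 2-fold. The split was 587 higher and 843 lower with scaling on the median. The count was 946 without control replicate 1 and 134 with normexp correction.

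With CD437, DHRS3 was again the gene with the largest rise. It rose 35.5-fold, to 2.79 ± 0.24 (change 5.15 ± 0.11, n = 3, adjusted p = 8.1e-10), SMPD3 by 3.36 ± 0.12 and CYP26A1 6.51-fold (2.70 ± 0.10, adjusted p = 9.98e-08). The bradykinin receptor BDKRB2 (2.56 ± 0.14) and ANG (2.50 ± 0.09) rose. PTPRH and RNASE4 (1 of 3 control arrays) and the transcription factor PAX4 (2 of 3) were at least 4.51-fold, 3.80-fold and 4.81-fold higher. HOXB2 was well above background neither with CD437 nor in the control. The ubiquitin-conjugating enzyme UBE2E1 (−1.98 ± 0.38), TNFRSF11B (−1.97 ± 0.19), CD36 (−1.70 ± 0.13), the histone chaperone HIRA (−1.57 ± 0.30) and the keratin KRT16 (−1.54 ± 0.34) fell, and ANXA1 and WNT2B were at least 5.17-fold and 2.68-fold lower (1 of 3 CD437 arrays). TAF5L had a change of −2.69 ± 0.80 (adjusted p = 0.0345). For TAF5L with CD437 the adjusted p was 0.0970, 0.0601 or 0.0895 without control replicate 1, 2 or 3 and 0.110 or 0.0694 without CD437 replicate 1 or 2. Of 25 retinoid-induced genes 16 rose and none fell, and adjusted over the list alone 17 rose, with a median of 0.55 (camera adjusted p = 8.39e-08, and adjusted p = 0.0613 with an estimated correlation). STRA6 was at least 3.38-fold higher (1 of 3 control arrays). Of 9 basal markers 5 fell and none rose, and adjusted over the list alone 5 fell and 1 rose, with a median of −0.37 (camera adjusted p = 0.00297, and adjusted p = 0.135 with an estimated correlation), among them KRT17 (−0.97 ± 0.18), CAV1 (−0.92 ± 0.08) and the laminin chain LAMC2 (−0.70 ± 0.12). RARG differed by 0.16 (adjusted p = 0.228, other probe −0.25) and RARA by −0.12 (95% interval −0.41 to 0.17, adjusted p = 0.527, other probe 0.71). Limma called 3995 genes (22.4%), 2613 higher and 1382 lower, of which 600 changed at least 2-fold. The split was 1368 higher and 2304 lower with scaling on the median and 2087 and 1993 with quantile normalization, and the median of all genes moved from 0.0723 to −0.0626 with scaling on the median. The count was 1691 without control replicate 1, 1495 without control replicate 3, 1912 and 2428 without CD437 replicate 1 and 2, 2016 with only the 6 arrays, 2605 with no filter on dim probes and 8 with normexp correction.

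The 3 retinoids were given at the same dose and time, so their responses were compared directly. Between AM580 and ATRA, no difference was found in DHRS3 (0.03, 95% interval −0.22 to 0.27, adjusted p = 0.966) or HOXB2 (−0.03, −0.30 to 0.25, adjusted p = 0.968), while for CYP26A1 the interval was −0.67 to −0.21 (−0.44, adjusted p = 0.0873) and for CYP26B1 0.19 to 0.82 (0.50, adjusted p = 0.170). Of 25 retinoid-induced genes 1 was higher and 1 lower with AM580, and adjusted over the list alone 2 and 2 (camera adjusted p = 0.221). Interferon genes were higher with AM580 than with ATRA, 9 of 24 called and none lower, and adjusted over the list alone 19, with a median of 0.44 (camera adjusted p = 1.38e-22, and adjusted p = 0.0326 with an estimated correlation). These included RSAD2 (0.97 ± 0.13), OAS2 (0.85 ± 0.10) and IFIT1 (0.69 ± 0.09). With normexp correction the median of the interferon response genes with AM580 and ATRA was 0.0210 (adjusted p = 0.852). Amino acid response genes were lower with AM580, 4 of 19, and adjusted over the list alone 13, with a median of −0.36 (camera adjusted p = 5.49e-20, and adjusted p = 0.00624 with an estimated correlation), among them DDIT4 (−1.19 ± 0.13), PHGDH (−1.04 ± 0.12) and the amino acid transporter SLC7A5 (−0.68 ± 0.09). The glutathione transferase GSTA5 was at least 3.52-fold lower with AM580, GSTA2 at least 4.68-fold (2 of 3 AM580 arrays), and PGC was lower too (−1.82 ± 0.12). FMO1, TAS2R9 and NRIP3 were at least 1.59-fold, 1.58-fold and 1.53-fold higher, with adjusted p-values of 0.0217, 0.0458 and 0.0347. These last calls were lost without 1 array. The highest adjusted p was 0.0991 (FMO1 with AM580 and ATRA) and 0.197 (TAS2R9 with AM580 and ATRA), both without ATRA replicate 1. For NRIP3 with AM580 and ATRA it was 0.141, without AM580 replicate 3. Limma called 155 genes (0.869%), 97 higher and 58 lower with AM580, of which 49 differed at least 2-fold. The split was 37 and 75 with scaling on the median, which moved the median of all genes from 0.0237 to −0.102, and 56 and 71 with quantile normalization. The count was 52, 99 or 82 without ATRA replicate 1, 2 or 3, 57, 84 or 53 without AM580 replicate 1, 2 or 3, and 0 with normexp correction.

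CD437 differed from both other retinoids in retinoid-induced genes. Against ATRA it left DHRS3 lower (−1.74 ± 0.11, 95% interval −1.98 to −1.50, adjusted p = 4.09e-06), CYP26A1 lower (−2.77 ± 0.10, −3.00 to −2.54, adjusted p = 7.52e-08) and CYP26B1 lower (−2.61 ± 0.14), with HOXB2 at least 11.8-fold lower. Of 25 retinoid-induced genes 15 were lower and 3 higher, and adjusted over the list alone 16 and 4, with a median of −0.42 (camera adjusted p = 1.99e-10, and adjusted p = 0.0254 with an estimated correlation). Of 24 interferon genes 19 were higher and none lower, also when adjusted over the list alone, with a median of 0.50 (camera adjusted p = 3.44e-09, and adjusted p = 0.226 with an estimated correlation), among them RSAD2 (1.03) and HERC6 (0.96). Of 19 amino acid response genes 9 were lower and 1 higher, and adjusted over the list alone 12 and 1, with a median of −0.34 (camera adjusted p = 3.22e-07, and adjusted p = 0.0823 with an estimated correlation), among them PHGDH (−0.97), and ASNS with 1 probe lower (−1.01) and another higher (0.54). The muscle caveolin CAV3 (1 of 3 ATRA arrays, adjusted p = 0.000146) and SLC7A8 were at least 6.46-fold and 3.21-fold higher. The arginine deiminase PADI2 was at least 4.46-fold higher (adjusted p = 0.0364). PGC (−3.40 ± 0.12) and the natriuretic peptide NPPC (−3.23 ± 0.15) were lower. For PADI2 with CD437 and ATRA the adjusted p was 0.102, 0.0557 or 0.0932 without ATRA replicate 1, 2 or 3. Against AM580, CD437 left DHRS3 lower (−1.77, 95% interval −2.01 to −1.52, adjusted p = 7.85e-06), CYP26A1 (−2.33, −2.56 to −2.10) and CYP26B1 (−3.11, −3.43 to −2.80) lower, HOXB3 lower (−2.53 ± 0.21) and HOXB2 at least 11.5-fold lower. Of 25 retinoid-induced genes 12 were lower and 2 higher, and adjusted over the list alone 15 and 3, with a median of −0.35 (camera adjusted p = 1.65e-11, and adjusted p = 0.0186 with an estimated correlation). SLC7A8 was at least 3.19-fold and the matrix protein THBS2 at least 3.51-fold higher, and CAV3 was higher (2.25 ± 0.32). For THBS2 with CD437 and AM580 the adjusted p was 0.0452, and it lay between 0.0644 and 0.134 without any 1 of the 6 arrays.

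Limma called 4302 genes between CD437 and ATRA (24.1%), 2770 higher and 1532 lower with CD437, of which 714 differed at least 2-fold, and 1713 between CD437 and AM580 (9.61%), 958 higher and 755 lower, of which 249 did. The split against ATRA was 1375 and 2911 with scaling on the median, which moved the median of all genes from 0.0749 to −0.0869, and 2159 and 2117 with quantile normalization. Against ATRA the count was 2252 and 2064 without ATRA replicate 1 and 3, 2445 and 2752 without CD437 replicate 1 and 2, 2393 with only the 6 arrays and 42 with normexp correction. Against AM580 it was 395 and 687 without AM580 replicate 1 and 3, 777, 876 and 3383 without CD437 replicate 1, 2 and 3, 644 with only the 6 arrays, 3323 with slide as a random block and 3 with normexp correction.

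The calls of the 3 retinoids overlapped. For ATRA and AM580, 533 genes rose with both, where independent lists would share 39.3, and 568 fell with both (34.5 for independent lists), while none moved opposite ways. For AM580 and CD437, 574 rose with both (127.8 for independent lists) and 270 fell with both (51.9), and 5 moved opposite ways. For ATRA and CD437, 447 rose with both (117.7) and 299 fell with both (71.2), and 18 moved opposite ways. These comparisons share their controls, and unchanged groups set against such controls gave a simulated correlation of fold changes across genes of 0.501, 0.503 and 0.499, beside 0.794, 0.617 and 0.411 observed, and at most 0.02 shared calls. The covariance was 0.133 for ATRA and AM580, 0.114 for AM580 and CD437 and 0.0764 for ATRA and CD437, against simulated values of 0.0169, 0.0169 and 0.0168, a difference of 0.116, 0.0967 and 0.0596. Part of the excess may come from the shared controls, as 3 arrays cannot be split into parts of 2. Genes are not independent replicates.

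R5020 left no gene past the threshold: limma called 0 of 16787, with a lowest adjusted p of 0.0812, and 2612 genes had an unadjusted p under 0.05. The receptor gene PGR differed by −0.25 (95% interval −0.62 to 0.12, n = 3, adjusted p = 0.50), and of 16 progestin-induced genes none passed, and adjusted over the list alone 1 rose, with a median of −0.05 and a mean of 0.04 (camera adjusted p = 0.395). Lists shifted without any member called over all genes. Of 17 hypoxia genes none passed, also when adjusted over the list alone, with a median of 0.26 (camera adjusted p = 0.000139, and adjusted p = 0.440 with an estimated correlation). Of 23 cholesterol synthesis genes 2 rose when adjusted over the list alone, with a median of 0.08, MSMO1 at 1.02 ± 0.19 (adjusted p = 0.10) and IDI1 at 0.80 ± 0.14 (adjusted p = 0.099), both enzymes of the pathway (camera adjusted p = 0.00186, and adjusted p = 0.440 with an estimated correlation). Of 21 glucocorticoid-induced genes 1 rose when adjusted over the list alone, with a median of 0.15, the receptor partner FKBP5 at 0.69 ± 0.13 (adjusted p = 0.11) and the kinase SGK1 at 0.59 ± 0.19 (camera adjusted p = 0.00192, and adjusted p = 0.440 with an estimated correlation). Of 8 metallothionein genes 5 fell when adjusted over the list alone, with a median of −0.49 (camera adjusted p = 0.0199, and adjusted p = 0.645 with an estimated correlation). Of 21 amino acid response genes 1 fell when adjusted over the list alone, with a median of −0.24 (camera adjusted p = 0.0359, and adjusted p = 0.645 with an estimated correlation). Of 30 mitosis genes none passed, with a median of 0.03 (camera adjusted p = 0.0477, and adjusted p = 0.629 with an estimated correlation). With normexp correction the medians of the cholesterol and mitosis lists turned to −0.302 and −0.341. Without R5020 replicate 1 the adjusted p was 0.149 for the amino acid response genes with R5020, 0.168 for the metallothionein genes with R5020 and 0.149 for the mitosis genes with R5020. Without R5020 replicate 2 it was 0.0656 for the amino acid and for the mitosis list. Without control replicate 3 it was 0.102, 0.0692 and 0.396 for these 3 lists and 0.0626 for the cholesterol synthesis genes with R5020, and without control replicate 2 it was 0.143 for the amino acid list and 0.0625 for the metallothionein list. The count was 2 without R5020 replicate 3, 38 with no filter on dim probes, 1 with the replicate number as a block, 1 with only the 6 arrays and 113 with all 33 arrays in 1 fit.

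With DEX, most genes known to be induced by glucocorticoids rose. EMP1, a membrane protein of epithelia, was at least 30.2-fold higher, at 0.52 ± 0.10 (n = 3; adjusted p = 6.17e-06), with 1 of 3 control arrays well above background (chromosome 12, 13260829 to 13260888, hg18). The repressor SNAI2 (3.23 ± 0.13) and the growth factor FGF18 (2.98 ± 0.14) rose. PGC (1 of 3 control arrays) was at least 5.79-fold, the mitochondrial glutamate carrier SLC25A18 and DOCK4 (2 of 3) at least 8.61-fold and 7.72-fold, and the sulfate transporter SLC26A2 and the decarboxylase DDC at least 3.92-fold and 3.71-fold higher. RAMP3, a partner of the calcitonin receptor, fell (−2.32 ± 0.20), and the amino acid transporter SLC43A1 (2 of 3 DEX arrays) and TMEM270 (1 of 3) were at least 4.68-fold and 3.21-fold lower. The transcription factor ETV4 was at least 2.99-fold, TAAR2 at least 2.56-fold, the mucin MUC5AC at least 2.52-fold, the immune ligand VTCN1 at least 2.44-fold and DMP1 at least 2.20-fold lower. Of 21 glucocorticoid-induced genes 16 rose and none fell, and adjusted over the list alone 17 rose, with a median of 0.92 (camera adjusted p = 9.4e-10, and adjusted p = 0.10 with an estimated correlation). These included FKBP5, a brake on the glucocorticoid receptor (2.02 ± 0.13), the monoamine oxidase MAOA (1.76 ± 0.17) and the repressor BCL6 (1.55 ± 0.19). Of 21 amino acid response genes 11 fell and none rose, and adjusted over the list alone 14 fell, with a median of −0.66 (camera adjusted p = 0.00865, and adjusted p = 0.479 with an estimated correlation), among them CHAC1 (−1.92 ± 0.17), PHGDH (−1.69 ± 0.17) and DDIT3 (−1.27 ± 0.19). Of 23 cholesterol synthesis genes 9 rose and 2 fell, also when adjusted over the list alone, with a median of 0.26 (camera adjusted p = 0.0282, and adjusted p = 0.479 with an estimated correlation), among them IDI1 (1.34 ± 0.14) and SQLE (1.15 ± 0.17). For the cholesterol synthesis genes with DEX the adjusted p was 0.0685 without DEX replicate 1. Of 22 interferon genes 11 fell and 2 rose, with a median of −0.40 (camera adjusted p = 0.0508), and of 16 progestin-induced genes 5 rose and 3 fell (camera adjusted p = 0.191). The receptor gene NR3C1 was higher by 0.55 (95% interval 0.14 to 0.96, adjusted p = 0.0321). For NR3C1 with DEX the adjusted p was 0.0525 and 0.101 without control replicate 1 and 3 and 0.0883 and 0.111 without DEX replicate 2 and 3, and with the trend on probe GC content removed the change was 0.155 (adjusted p = 0.425).

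Limma called 7913 of 16787 genes (47.1%), 3048 higher and 4865 lower with DEX, of which 420 were at least 2-fold higher and 1353 at least 2-fold lower. Changes with DEX followed the GC content of the probe, with a Spearman correlation across genes of −0.615 and a median change of 0.295 in the third of genes with the lowest GC content and −0.628 in the third with the highest. With each array's trend on GC content removed, an alternative added after the data were seen, 5110 genes were called, 2489 higher and 2621 lower, 3695 of them called in the same direction before, with 230 higher and 609 lower at 2-fold. With scaling on the median 4959 were higher and 2529 lower, and 1180 and 557 at 2-fold, so the balance of rises and falls turned, as the median of all genes moved from −0.122 to 0.156. With normexp correction 4 genes were called.

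**Figure D3:**
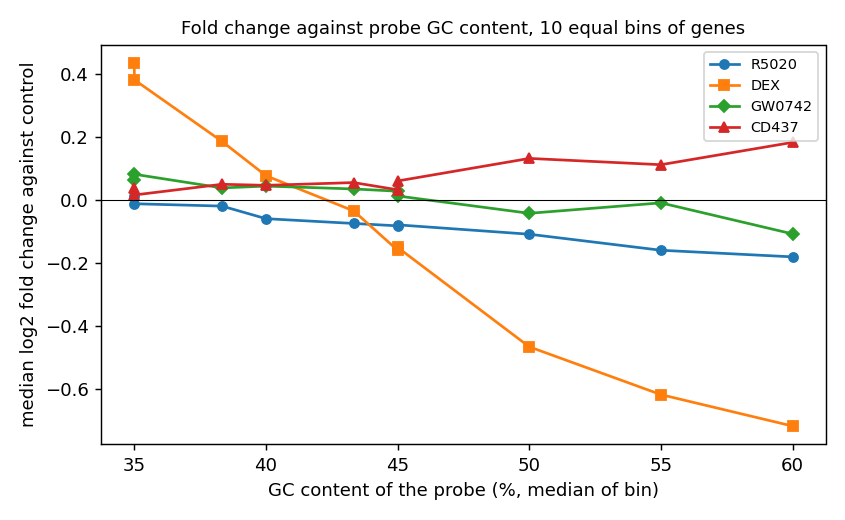
Lines give the median log2 fold change against control of genes in 10 bins of equal size by the GC content of their probe (percent), for R5020, DEX, GW0742 and CD437. The line of DEX falls from the lowest to the highest GC content, with medians of 0.295 over the third of genes with the lowest content and −0.628 over the third with the highest.

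R5020 at 10 nM and DEX at 100 nM, doses that differ, were compared through their treated cells. EMP1 (−3.74 ± 0.24, adjusted p = 8.22e-05) and SNAI2 (−3.43 ± 0.13, adjusted p = 1.59e-06) were lower with R5020 than with DEX, and PGC was at least 5.02-fold lower. VTCN1 and ANO8 were at least 2.15-fold and 2.06-fold higher, as was TMEM86A at least 2.61-fold (adjusted p = 0.0201). For TMEM86A with R5020 and DEX the adjusted p was 0.0516 without DEX replicate 1 and 0.0553 without DEX replicate 2. Of 21 glucocorticoid-induced genes 15 were lower and none higher with R5020, also when adjusted over the list alone, with a median of −0.64 (camera adjusted p = 8.24e-07, and adjusted p = 0.229 with an estimated correlation), among them MAOA (−1.82) and BCL6 (−1.78). Of 22 interferon genes 12 were higher and 1 lower, and adjusted over the list alone 13 and 1, with a median of 0.58 (camera adjusted p = 0.00379, and adjusted p = 0.577 with an estimated correlation), among them IFI6 (1.36) and OAS1 (1.12). Limma called 7102 genes (42.3%), 3913 higher and 3189 lower with R5020, of which 1040 differed at least 2-fold. The split was 2118 and 4037 with scaling on the median, which moved the median of all genes from 0.0641 to −0.101. The count was 3868 without R5020 replicate 2, 4563 and 3698 without DEX replicate 2 and 3, 4322 with the trend on GC content removed and 1 with normexp correction. Fold changes of R5020 and DEX against their shared controls had a covariance across genes of 0.0709, against a simulated 0.0194 with no effect, and a correlation of 0.396 against a simulated 0.50.

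The arrays of GW0742 were set against the libraries labelled GW0742 control. PDK4, which turns off pyruvate dehydrogenase (2.45 ± 0.13, adjusted p = 0.00013), and ANGPTL4, which inhibits lipoprotein lipase (2.29 ± 0.06, adjusted p = 3.2e-05), rose. CALCR, the calcitonin receptor, rose 14.0-fold, from −2.90 ± 0.27 to 0.90 ± 0.07 (n = 3; change 3.80 ± 0.14, 95% interval 3.46 to 4.14, adjusted p = 7e-05), at chromosome 7, 92892005 to 92892064 (hg18). The gap junction protein GJA1 (3.13 ± 0.10), the corneodesmosin CDSN (2.93 ± 0.11) and N-cadherin CDH2 (2.68 ± 0.06) rose, and AGR3, ART4, RAMP3 and KLHL4 were at least 4.79-fold, 4.02-fold, 3.92-fold and 3.86-fold higher. Genes that ATRA raised were among the largest falls. DHRS3 lay at −3.52 ± 0.36 with GW0742 and at 2.76 ± 1.61 in the libraries labelled control (change −6.29 ± 0.77, 95% interval −8.16 to −4.41, adjusted p = 0.00177). CYP26A1 lay at −2.66 ± 0.03 and 1.45 ± 2.12 (change −4.11 ± 0.99, adjusted p = 0.0168), and for CYP26A1 with GW0742 the adjusted p was 0.0545 without control replicate 3. HOXB2 was at least 14.8-fold, the transcription factor TP63 at least 11.4-fold, STRA6 at least 11.2-fold, the noncoding RNA H19 at least 10.4-fold and the matrix link protein HAPLN1 at least 7.65-fold lower, as was HOXB3 at least 11.7-fold (1 of 3 GW0742 arrays). The libraries labelled GW0742 control stood apart from the other 3 control groups: 199 genes raised at least 2-fold by ATRA lay there at a median of 0.343, 0.787 and 0.902 above the mean of those groups, and in the GW0742 arrays at −0.156, −0.109 and −0.142. Against the retinoid control alone the latter lay above 0. Against the E2 control arrays (added after the data were seen), DHRS3 fell (−2.40), as did TP63, HOXB2, H19 and HAPLN1. PDK4 (2.87), ANGPTL4 (2.32), GJA1 (3.47), CDH2 (3.31), CDSN (2.54), CALCR (2.10), ART4 and KLHL4 rose. There the sign turned for RAMP3 with GW0742 (−0.0501), AGR3 with GW0742 (−0.0772) and CYP26A1 with GW0742 (0.24). HOXB2 was high in the E2 control (−2.70), and with GW0742 (−5.42) it was not below the retinoid (−6.06) or R5020 and DEX control (−5.71).

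Of 18 PPAR target genes, mostly of fatty acid use, 12 rose and 1 fell with GW0742, and adjusted over the list alone 13 and 1, with a median of 0.35 (camera adjusted p = 0.00121, and adjusted p = 0.559 with an estimated correlation). Besides PDK4 and ANGPTL4 these included the carnitine carrier SLC25A20 (1.07 ± 0.07) and catalase CAT (0.79 ± 0.07). Of 24 interferon genes 19 fell and 2 rose, also when adjusted over the list alone, with a median of −0.82 (camera adjusted p = 3.6e-07, and adjusted p = 0.559 with an estimated correlation), among them the antiviral MX1 (−3.03 ± 0.11) and IFIT3 (−1.57 ± 0.15). Of 23 retinoid-induced genes 12 fell and 3 rose, also when adjusted over the list alone, with a median of −0.93 (camera adjusted p = 0.00928, and adjusted p = 0.559 with an estimated correlation). Of 12 immediate early genes 10 rose and 1 fell, also when adjusted over the list alone, with a median of 0.66 (camera adjusted p = 0.00403, and adjusted p = 0.559 with an estimated correlation), among them KLF6 (1.32 ± 0.09) and FOS (1.29 ± 0.17). Of 23 cholesterol synthesis genes 12 rose and 1 fell, and adjusted over the list alone 13 and 1, with a median of 0.23 (camera adjusted p = 0.00403, and adjusted p = 0.559 with an estimated correlation), among them SQLE (0.58 ± 0.10) and INSIG1 (0.55 ± 0.06). Of 35 DNA replication genes 14 fell and 2 rose, and adjusted over the list alone 14 and 1, with a median of −0.20, which turned to 0.0263 with scaling on the median (camera adjusted p = 0.00364, and adjusted p = 0.638 with an estimated correlation), among them ORC6 (−1.06 ± 0.11). Against the E2 control arrays the median was −0.161 for the interferon response genes with GW0742 (adjusted p = 0.0414), 0.290 for the PPAR target genes with GW0742 (adjusted p = 0.0704), −0.0670 for the retinoid-induced genes with GW0742 (adjusted p = 0.718) and −0.0106 for the cholesterol synthesis genes with GW0742 (adjusted p = 0.894). Among genes not called with any retinoid the adjusted p was 0.0566 for PPAR targets, 0.0570 for cholesterol synthesis and 0.227 for the immediate early genes with GW0742. Against the E2 control arrays the calls of SLC25A20, SQLE, INSIG1, IFIT3, FOS and ORC6 were lost. The receptor gene PPARD differed by −0.05 (95% interval −0.18 to 0.08, adjusted p = 0.472), whereas its other probe was called lower (−0.57).

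Limma called 9106 of 18433 genes (49.4%), 4928 higher and 4178 lower with GW0742, of which 293 were at least 2-fold higher and 889 at least 2-fold lower. Against the E2 control arrays the count was 3128, 1908 higher and 1220 lower, and with all 33 arrays in 1 fit it was 4270. With scaling on the median 8796 were higher and 2312 lower, and 565 and 579 at 2-fold, as the median of all genes moved from 0.0197 to 0.246.

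Across the ligands, 21 pairs of call lists were compared. ATRA and GW0742 called 716 genes in opposite directions and 288 in the same, with 310 genes that rose with ATRA and fell with GW0742 (167.7 for independent lists) and 406 that fell with ATRA and rose with GW0742 (245.4). AM580 and CD437 showed 628 and 1746 opposite calls with GW0742, and 192 and 408 in the same direction. Opposite calls can come from the libraries labelled GW0742 control, where genes raised by ATRA were high. With the E2 control arrays as control the opposite calls were 303 for ATRA, 252 for AM580 and 531 for CD437, beside 178, 152 and 224 in the same direction, and DEX and GW0742 turned to 779 and 583. E2 and ATRA shared 90 calls in the same direction, 30 that rose (9.76 for independent lists) and 60 that fell (19.6). Of 140 opposite calls, 53 rose with E2 and fell with ATRA (11.8) and 87 the reverse (16.1). E2 shared 58 calls in the same direction with AM580, 47 with CD437, 122 with DEX and 195 with GW0742, against 127, 129, 163 and 202 opposite. DEX and GW0742 shared 2318 in the same direction and 1628 opposite, ATRA and DEX 432 and 315, and CD437 and DEX 440 and 1271. At 2-fold or more the balance turned in 2 pairs, to 24 in the same direction and 30 opposite for ATRA and DEX and to 66 and 42 for E2 and GW0742. No gene was called in 1 direction under all 7 ligands, since limma called none for R5020, where 2612 had an unadjusted p under 0.05. Among 15654 genes tested in all fits, CCDC74B rose and the protease PLAU and the sialyltransferase ST8SIA4 fell with at least 1 ligand in each of the 4 experiments, where independent lists would give 1.68 and 2.43 genes. With quantile normalization the numbers were 2 and 0. Of the 46 list calls in the 7 comparisons against controls, 9 held with an estimated correlation: estrogen-repressed genes with E2, retinoid-induced, estrogen-repressed, interferon, amino acid response, immediate early and basal genes with ATRA, and retinoid-induced and basal genes with AM580.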

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

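The settings chosen only after the data were seen were normexp followed by quantile normalization, the removal of each array's trend on probe GC content, the slide block over 6 arrays, the E2 slide of replicate 2 left out, the E2 control arrays in place of those labelled GW0742 control, and the genes not called for a retinoid. All other settings were planned. Of the named genes, 358 kept direction and side of the threshold with quantile normalization and 8 lost their call, 348 and 15 did so with scaling on the median, 318 and 34 in the authors' value table, 329 and 25 with normexp followed by quantile normalization, 321 and 49 with no filter on dim probes, and 158 and 180 with normexp alone. Normexp adds a fixed offset of 50 to signals whose 75th percentile ran from 91.1 to 960, so it narrows changes by unequal amounts on different arrays, and most counts returned when quantile normalization followed it. Signal over background limits all dim genes. Bounds are given for those named, while tests, list medians and values under other settings use the signals as they stand. For list tests the 2-fold threshold does not enter the test, and the slide as a random block was not applied to them, so neither has a value.

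With normexp correction the counts of genes called were 22 for E2, 157 for ATRA, 134 for AM580, 8 for CD437, 4 for DEX, 0 between AM580 and ATRA, 42 between CD437 and ATRA, 3 between CD437 and AM580 and 1 between R5020 and DEX. With normexp followed by quantile normalization they were 402 for E2 and 2674 between CD437 and AM580, and in the table of the authors' values they were 344 and 2704, where the cause was not tested. With no filter on dim probes, which adds genes to the test, they were 139 for E2, 2605 for CD437, 38 for R5020 and 1092 between CD437 and AM580. With the filter applied on every array, which leaves fewer genes, they were 448 for E2 and 97 between AM580 and ATRA. With all 33 arrays in 1 fit, which pools the spread over other experiments, they were 4449 for E2, 113 for R5020, 4270 for GW0742 and 1126 between CD437 and AM580. With only the 6 arrays of a comparison, which leaves fewer arrays to estimate spread, they were 2016 for CD437, 1 for R5020, 97 between AM580 and ATRA, 2393 between CD437 and ATRA and 644 between CD437 and AM580. With slide as a random block (estimated correlation −0.0990) they were 252 between AM580 and ATRA and 3323 between CD437 and AM580, where the cause was not tested. With the trend on GC content removed they were 5110 for DEX and 4322 between R5020 and DEX. Against the E2 control arrays GW0742 gave 3128. At 2-fold or more, a stricter rule by construction, they were 417 for ATRA, 400 for AM580, 600 for CD437, 1773 for DEX, 1182 for GW0742, 49 between AM580 and ATRA, 714 between CD437 and ATRA, 249 between CD437 and AM580 and 1040 between R5020 and DEX, and at 1.5-fold 0 genes moved 1 way in each experiment. List calls numbered 9 with an estimated correlation and 77 with fry, against 46. In 5 of 21 pairs of ligands more calls ran the same way than opposite, and the number was 5 at 2-fold and with quantile normalization. At 2-fold the pairs were not the same, since ATRA and DEX turned, as did E2 and GW0742. With GW0742 set against the E2 control arrays the number was 4, as DEX and GW0742 turned.

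With the replicate number as a block the counts were 1472 for E2, 1 for R5020 and 102 between AM580 and ATRA, and within 1.5 times the main count elsewhere. For E2 they were 1649 with the block and the GC trend removed, and 1465 without the slide of replicate 2. For ATRA the slide block over 6 arrays gave 3298, and 3634 with the GC trend removed too. Only E2 and ATRA are paired through slides, and in their groups each array correlated best with its own number, whereas in no other comparison did each do so. In the block, TOP2A, BUB1B, RAI14, HMGCR, MSMO1, DDIT4, SLC7A11, NOP56, HSP90AA1, AGR2 and MUC1 were called with E2, TGM2 with E2 and POLA2 and MCM10 with ATRA lost their call, and the p53 list with E2 had an adjusted p of 0.0561. Among comparisons that share only numbers, the estrogen-repressed list, CENPA and ESR1 with AM580, NR3C1 with DEX, CD3E with GW0742 and NRIP3, FMO1, TAS2R9, ELF3 and RBP1 between AM580 and ATRA lost theirs. The block changed no other call of a named gene or of a list called without it.

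With 1 array left out at a time, the counts ran from 144 to 889 for E2, 1121 to 1345 for ATRA, 946 to 1224 for AM580, 1495 to 5847 for CD437, 0 to 2 for R5020, 5567 to 8897 for DEX, 6365 to 9426 for GW0742, 52 to 99 between AM580 and ATRA, 2064 to 5978 between CD437 and ATRA, 395 to 3383 between CD437 and AM580 and 3698 to 6590 between R5020 and DEX, and list calls from 42 to 51. Fewer arrays leave less power by construction, while the rises above the main counts were not explained and their cause was not tested. Over these fits, calls of named genes held or stayed absent in 2018 instances, were lost in 191 and gained in 13.

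Directions turned mostly with normexp. The medians of metallothionein genes with AM580 (−0.0799), mitosis genes with R5020 (−0.341) and cholesterol synthesis genes with R5020 (−0.302) turned. For AM580 the values were 0.357 for SLC7A8, 0.204 for ANXA1, 0.0384 for RARG, 0.657 for EGR2, −0.0227 for MT2A, −0.0513 for MT1G, 0.154 for KRT17, 0.678 for MYLK, 0.602 for TP63, −0.0783 for ESR1, 0.397 for NR2F1 and −0.103 for NR2F2. For CD437 they were 0.0399 for WNT2B and 0.176 for TP63, for ATRA 0.00636 for STARD4 and 0.0374 for MYLK, and for E2 0.0408 for RSAD2. For R5020 they were 0.408 for PGR, −0.0334 for KIF20A, 0.365 for ZBTB16, −0.0683 for LDLR, 0.511 for ALDH1L2 and 0.199 for SLC7A11, and for GW0742 0.0397 for ITGAM and 0.0948 for CD3E. Between AM580 and ATRA they were 0.340 for GSTA5, 0.117 for GSTA2, 0.490 for HOXA1, 0.158 for STRA6, 0.228 for HOXB2 and −0.644 for DHRS3, between CD437 and AM580 −0.280 for SLC7A8 and −0.184 for THBS2, and between R5020 and DEX 0.125 for ZBTB16. The difference for DHRS3 with AM580 and ATRA also turned in the authors' value table (−0.113), with scaling on the median (−0.10), with normexp and quantile normalization (−0.146) and with the GC trend removed (−0.00108). RARG with AM580 turned in the authors' value table (0.000895), without AM580 replicate 1 (0.00861) and without retinoid control replicate 1 (0.00622), over a range that reached −0.0322 without control replicate 3, and PPARD with GW0742 turned with scaling on the median (0.178). Left-out arrays also turned HOXB2 between AM580 and ATRA (0.0812 without AM580 replicate 3, 0.0451 without ATRA replicate 2, 0.0103 without ATRA replicate 3, and down to −0.136 without ATRA replicate 1) and ZBTB16 with R5020 (0.818 without control replicate 3, and down to −1.40 without control replicate 2). Against the E2 control arrays the values for GW0742 were −0.0106 for cholesterol synthesis genes, −0.0501 for RAMP3, −0.0772 for AGR3, 0.240 for CYP26A1, 0.0141 for PPARD, −0.0414 for HSD17B7, 0.223 for XAF1 and 0.464 for CD14. The retinoid-induced list with GW0742 had a median of 0.215 without genes called for a retinoid, as its changed members are left out by construction. For the other turned values the cause was not tested.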

Other observations

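With the retinoids, several genes of nuclear receptors and of luminal epithelium changed, although neither list passed as a whole. The orphan receptor NR4A3 rose by 2.29 ± 0.12 with ATRA, 2.66 ± 0.12 with AM580 and 1.03 ± 0.12 with CD437 (SE, n = 3; limma adjusted p = 2.9e-07, 1.3e-07 and 0.00071), and PPARG, a receptor known from fat cells, by 0.76 ± 0.08 with ATRA and 1.15 ± 0.08 with AM580. Of 26 nuclear receptor genes 3 rose and 2 fell with ATRA, 4 rose with AM580 and 2 rose with CD437, and adjusted over the list alone 3 rose and 2 fell, 5 rose and 4 fell, and 2 rose (camera adjusted p = 0.800, 0.861 and 0.978). Among 15 luminal markers the transcription factors FOXA1 (1.06 ± 0.09 with ATRA, 0.90 ± 0.09 with AM580) and SPDEF (0.81 ± 0.08 with ATRA, 0.90 ± 0.08 with AM580, 0.68 ± 0.08 with CD437) rose, where 2 rose and 1 fell with ATRA, 3 rose with AM580 and 2 rose and 1 fell with CD437 (camera adjusted p = 0.742, 0.803 and 0.978). Adjusted over the list alone 2 rose and 3 fell, 3 rose and 2 fell, and 2 rose and 1 fell. Of 21 p53 target genes 3 rose and 1 fell with ATRA, 3 rose and 2 fell with AM580 and 7 rose and 3 fell with CD437 (camera adjusted p = 0.742, 0.663 and 0.860), and adjusted over the list alone 3 and 2, 3 and 2, and 7 and 5. BTG2, which slows the cell cycle, rose by 2.45 ± 0.10 with ATRA, 2.32 ± 0.10 with AM580 and 0.93 ± 0.10 with CD437, and the cell cycle inhibitor CDKN1A fell by 0.50 (SE 0.08) with ATRA and by 0.53 (SE 0.08) with AM580.

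With E2, 18 ribosome biogenesis genes had a median change of 0.55, with none called over all genes and 6 higher when adjusted over the list alone (camera adjusted p = 7.36e-06, and adjusted p = 0.187 with an estimated correlation). For 10 heat shock genes the median was 0.40, with none called either way (camera adjusted p = 0.00984, and adjusted p = 0.187 with an estimated correlation). Of 20 amino acid response genes 1 rose, and adjusted over the list alone 7 rose and 1 fell (median 0.40, camera adjusted p = 0.0302, and adjusted p = 0.187 with an estimated correlation), and 23 cholesterol synthesis genes had a median of 0.38 with none called either way (camera adjusted p = 0.00631, and adjusted p = 0.308 with an estimated correlation). Of 21 p53 target genes 2 fell, and adjusted over the list alone 3 (median −0.25, camera adjusted p = 0.0386, and adjusted p = 0.187 with an estimated correlation), of 13 luminal markers 2 fell, and adjusted over the list alone 4 fell and 1 rose (median −0.26, camera adjusted p = 0.0386, and adjusted p = 0.339 with an estimated correlation), and of 22 retinoid-induced genes 2 fell and 1 rose, and adjusted over the list alone 8 and 2 (median −0.39, camera adjusted p = 0.0134, and adjusted p = 0.187 with an estimated correlation). For 23 interferon genes the median was −0.41 with none called either way (camera adjusted p = 0.0134, and adjusted p = 0.542 with an estimated correlation), and on the 3 slides it was −0.873, 0.0153 and −0.414. With slides as blocks the nuclear receptor list had an adjusted p of 0.0415 (0.0597 without, 0.187 with an estimated correlation) and the p53 list of 0.0561. Without E2 replicate 1 the adjusted p was 0.0794 for the amino acid response genes with E2, 0.0515 for the cholesterol synthesis genes with E2, 0.169 for the interferon response genes with E2 and 0.107 for the p53 target genes with E2. Without E2 replicate 2 it was 0.154 for the luminal epithelial markers with E2 and 0.0565 for the retinoid-induced genes with E2, and without E2 replicate 3 it was 0.0993 for the interferon list. Without E2 control replicate 1, 2 or 3 it was 0.0638, 0.0564 or 0.0546 for the luminal list, without control replicate 2 or 3 it was 0.0526 or 0.0598 for the p53 list, and without control replicate 2 it was 0.0714 for the amino acid list. Of leukocyte markers 4 of 6 fell with GW0742, also when adjusted over the list alone, with a median of −0.67 (camera adjusted p = 0.0173, and adjusted p = 0.559 with an estimated correlation), among them the endotoxin receptor CD14 (−0.77 ± 0.15) and LCP1 (−0.57 ± 0.08), and against the E2 control arrays CD14 with GW0742 turned to 0.46.

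Of the tests that follow, those of other splits of the arrays were planned before the data were examined. Removal of the GC trend was added after that, with its prediction written before its result was seen. All other tests were chosen after the result was seen. The first pattern was that genes raised by ATRA were lower in the GW0742 arrays than in the libraries labelled GW0742 control. Their median change was −0.7859 over 199 genes, outside the range of 1000 random lists (−0.137 to 0.0899), with 126 called lower and 15 called higher, which speaks against a shift of slide or scan that moves genes regardless of their response to retinoids. Against the mean of the other 3 control groups the same genes lay 0.7867 higher in the libraries labelled GW0742 control (median of 3 arrays) and at −0.142 in the GW0742 arrays, which lay at 0.276, 0.283 and 0.285 against the retinoid control alone and at −0.214 to −0.258 against the other 2 groups. Retinoid exposure of those controls, or a wrong label, is a candidate explanation, and the design text mentions ATRA beside GW0742. The 177 genes lowered by ATRA lay at 0.143, −0.0697 and −0.231 in those controls, not commonly low as exposure predicts. They rose with GW0742 (median 0.4027), to 0.203, 0.268 and 0.260. Whether GW0742 itself lowers retinoid-raised genes below untreated cells stays open, because the other control groups lie on other slides.

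A second pattern was that DEX called 7913 genes and R5020 none against the same control arrays. With each array's trend on probe GC content removed DEX called 5110, 3695 of them as before and 839 against 1773 at 2-fold, and with quantile normalization 7512, which speaks against either trend as the whole cause, while GC content may account for much of it. The slide and scan day of the DEX arrays, which hold that group alone, stay open and may account for part of the count. Since R5020 and DEX arrays also lie on different slides, the 7102 genes that differ between them cannot be told apart from a slide effect. An effect of dexamethasone through its receptor, which the design names, stays among the open explanations and was not tested further.

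The third pattern was that genes raised by E2 stood at unequal levels in the 4 control groups. Relative to the E2 control, 206 such genes had medians of 1.20, 1.1 and 1.14 in the retinoid control arrays and 1.31, 1.37 and 1.22 in the R5020 and DEX control arrays, against 1.51, 1.51 and 1.52 with E2 itself and −0.209, −0.165 and −0.136 in the GW0742 control. A difference of scanner or software version is argued against by the retinoid control (median of its arrays 1.138), scanned like the E2 control. Only its replicate 2 (1.1) also shared the extraction protocol. The 368 genes lowered by E2 were lower in both groups too, with −0.9405 in the R5020 and DEX control as the smaller shift, so more estrogen activity in these cultures is a candidate explanation. It was found and tested on the same data.

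For each of the 11 comparisons, the 6 arrays can be split into 3 against 3 in 10 ways, and 10 splits cannot give a share under 0.05. The labelled split gave 699 genes for E2, 1541 for AM580, 3995 for CD437, 7913 for DEX, 9106 for GW0742, 4302 between CD437 and ATRA and 7102 between R5020 and DEX, with 0 in the highest other split of each, and 1 split reached the labelled count. It gave 1722 for ATRA and 155 between AM580 and ATRA, with 1 in the highest other split, and 1713 between CD437 and AM580, with 7. For R5020 all 10 splits gave 0 genes with limma, where the labelled one had 2612 with an unadjusted p under 0.05.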
